A study of Mus musculus with 8 samples.

How the data were processed

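RNA was measured in NIH 3T3 cells, an established mouse embryonic fibroblast line, that carried 1 of 3 retroviral constructs. These encoded EN (the ETV6-NTRK3 fusion), a kinase-dead form of it (EN-KD) or no insert (Vector). EN joins part of the transcription factor ETV6 to the tyrosine kinase domain of the neurotrophin receptor NTRK3. Per the labels' protocols, total RNA was extracted with Trizol and biotinylated cRNA was hybridised to Affymetrix MOE430A arrays, which read each transcript with 1 or more probe sets.

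The deposited table holds 1 linear intensity per probe set and array, for 22690 probe sets on 8 arrays. The software, background correction and scaling behind the values are not given in the sources used here, and the table carries no detection calls. The values were never negative, and between 15 and 31 probe sets per array were listed at 0. Array medians lay between 284.77 and 304.17 intensity units, so scaling between arrays before deposit stays possible but unstated. No pair of columns was identical, and replicate arrays correlated across probe sets with r from 0.979 to 0.990.

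The 64 Affymetrix control probe sets were left out. Intensities were taken as log2(value + 30.224), where the pseudocount is the percentile 10 of all positive values. Array medians differed by at most 0.0862 on the log2 scale, so no further normalization was applied, under a rule that asked for quantile normalization only at larger differences. All folds below are on this scale and understate changes of dim genes. Probe sets in the lowest 25% of mean log2 value were left out, which left 16969. Of the 22626 probe sets that are not controls, 20380 had 1 gene symbol in the platform annotation, 691 had several and 1555 had none. Gene identifiers matched 20351 of them to the RefSeq table of assembly GRCm38.p6, and 0 symbols changed. That table served for names only, and no coordinates are given because the sources name no genome build. For each gene the probe set with the highest mean was kept, which gave 10037 genes.

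The labels name 2 EN samples, 1 EN-KD sample and 1 Vector sample, each with 2 replicate arrays. They do not say whether replicate arrays came from separate cultures. For EN against controls, the 2 arrays of each labelled sample were therefore averaged, and 2 EN samples were compared with 2 control samples (EN-KD and Vector) by limma (version 3.58.1 in R 4.3.3) with a mean-variance trend. The p-values of this comparison rest on the spread between the 2 EN samples and between EN-KD and Vector. These 2 controls carry different constructs and are not replicates, so that spread can hold construct differences as well as culture differences. The other 4 comparisons used limma on 4 group means over 8 arrays with 4 residual degrees of freedom. Their p-values measure only the spread between replicate arrays, which may be technical. All tests were two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05, and SE is limma's moderated standard error.

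Before the data were examined, 28 gene lists, the rule for named genes and the processing alternatives were fixed. A list was tested with limma's camera where at least 5 members were measured, with a preset correlation of 0.01 between genes and, beside it, an estimated correlation. For EN against controls that estimate rests on 2 residual degrees of freedom, so a call lost with it does not decide about a list. Called means an adjusted p under 0.05 over all genes tested, and counts adjusted over the list alone stand beside it. The named genes are the 12 largest increases and 12 largest decreases for EN against controls, and the 5 largest each way for every other comparison, among called genes whose arrays did not overlap between the groups. Each list adds up to 4 called members of largest change, or its 2 largest as values only where fewer than 2 were called. Etv6 and Ntrk3 are always given. Genes named outside this rule are marked as chosen after their values were seen.

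The alternatives were other pseudocounts (1, or the percentile 25 of positive values, 92.236), quantile normalization, centring each array on its median, no filter, a filter at 50%, all probe sets, no mean-variance trend, each array left out in turn (added later for the hypoxia list in EN-KD against Vector and for 9 genes between the EN samples), other treatments of the replicate arrays, and each labelled sample left out. The procedure was tested on simulated data for 10037 genes, in 10 simulations with 200 changed genes each. For EN against controls it recovered 1.94% of genes changed by 0.5 on the log2 scale, 67.5% of those changed by 1 and 96.4% of those changed by 2, and 3.93% of its calls were false. For EN against EN-KD it recovered 33.6%, 87.6% and 99.2%, with 4.86% false calls. The simulated data for that comparison held no spread between cultures. Its false share therefore does not cover differences between the EN-KD culture and the EN cultures. For EN against controls, the simulated spread between cultures was drawn separately for each gene, from the spread in these data. The 3.93% false calls there do not cover culture shifts that many genes share. The number of samples thus limits the precision, and small changes were mostly out of reach. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.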

Results

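Gene expression was profiled in monolayer cultures of NIH 3T3 fibroblasts that carried the EN fusion, its kinase-dead form or the empty vector. The 8 arrays fell into 4 groups of 2 replicate arrays: EN sample 1, EN sample 2, EN-KD and Vector. The design asks what the active fusion kinase changes, with EN-KD as the control for the protein without its kinase activity and Vector as the control for transduction. Precision was limited by the number of arrays and, for EN against controls, by 2 labelled samples on each side.

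Cells with active EN carried far higher levels of several interferon-inducible GTPases than the controls. Gbp3, a guanylate-binding protein, was 9.87-fold higher (log2 difference 3.30 ± 0.17 SE, adjusted p = 0.000148, n = 2 samples per arm). Iigp1, Ifi47, Igtp and Irgm2, members of the immunity-related GTPase family, were 6.89-fold, 5.86-fold, 3.49-fold and 3.28-fold higher. Gbp2 rose 5.09-fold and Oasl2, an oligoadenylate synthetase-like gene, rose 3.72-fold. The other genes with the largest increases were Upp1, the uridine phosphorylase of pyrimidine salvage (9.47-fold, log2 3.24 ± 0.34), Il33, an alarmin cytokine (6.33-fold, log2 2.66 ± 0.18), and Ngef (5.47-fold, log2 2.45 ± 0.21). Akr1c18, an aldo-keto reductase that inactivates progesterone, rose 4.77-fold, and Rgs16, which dampens G protein signalling, rose 4.16-fold. By the rule that named these 12 genes, every one of the 4 EN arrays lay above all 4 control arrays. Gbp3 averaged 20.35 intensity units in controls, below the pseudocount, so its log2 difference ranged from 2.32 to 4.48 over the alternatives. Without Vector replicate 2, Rgs16 (adjusted p = 0.0688) and Irgm2 (adjusted p = 0.105) were no longer called.

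The strongest decreases were in a water channel, in chemokines and in secreted proteins. Aqp1, an aquaporin, was 12.9-fold lower in EN (log2 difference -3.69 ± 0.19 SE, adjusted p = 0.000148, n = 2 samples per arm). The neutrophil-attracting chemokines Cxcl5 (log2 -3.56 ± 0.36) and Cxcl1 (log2 -3.03 ± 0.32) and the monocyte chemokine Ccl7 (log2 -2.55 ± 0.22) fell together with Ptx3, a long pentraxin (log2 -3.25 ± 0.24). Slpi, a secreted protease inhibitor, differed by -2.72 ± 0.18, Postn (periostin) by -2.49 ± 0.17 and Lpl (lipoprotein lipase) by -2.13 ± 0.22, all called, although another Lpl probe set gave -1.07 (adjusted p = 0.107). Tfec, a transcription factor of the MiT family (log2 -3.22 ± 0.22), and Sod3, the extracellular superoxide dismutase (log2 -2.51 ± 0.20), averaged 28.7 and 27.1 intensity units in EN, below the pseudocount. C1ra, a complement protease, differed by -2.07 ± 0.28 and Tmem176a by -1.98 ± 0.29. By the same rule, all 4 EN arrays lay below all 4 control arrays for each of these 12 genes.

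**Figure D1:**
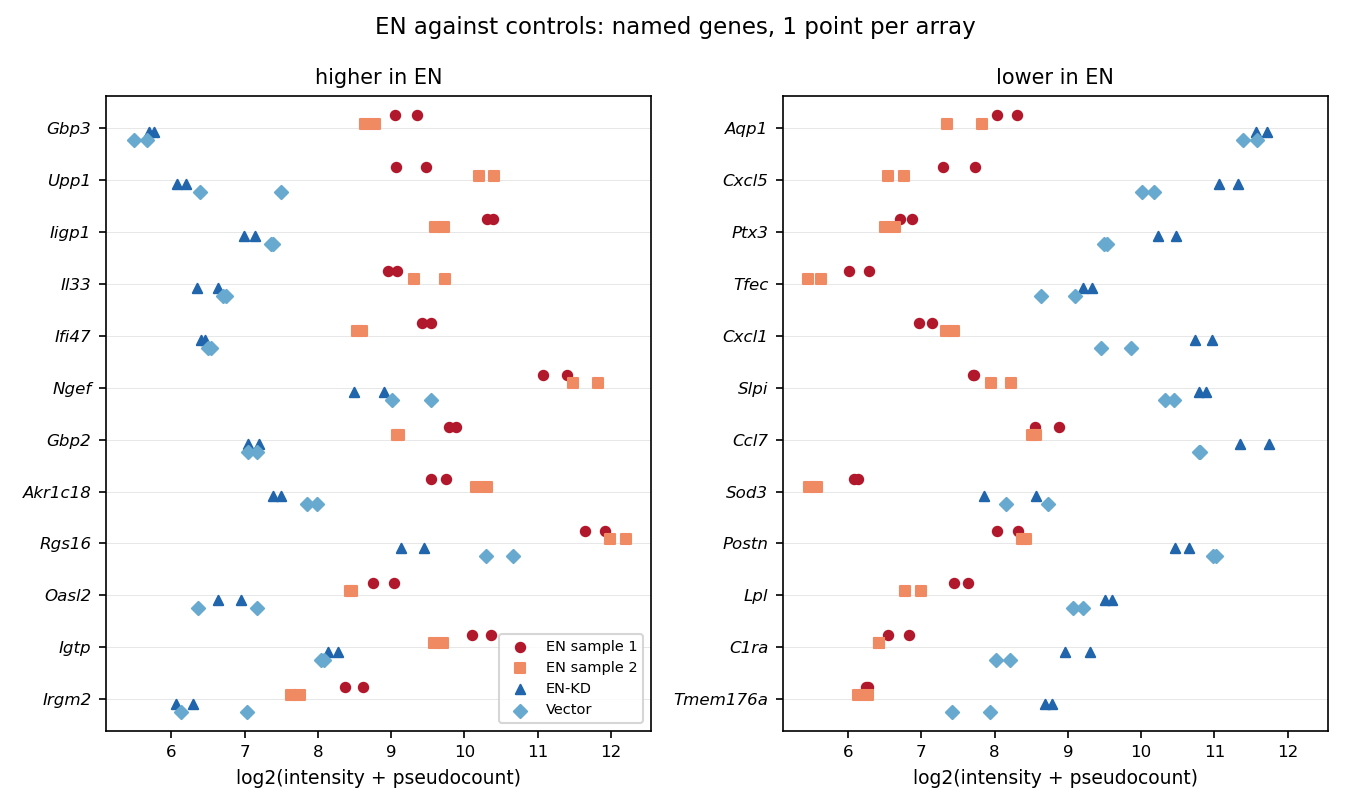
Log2(intensity + pseudocount) of the 12 genes with the largest increases (left) and the 12 with the largest decreases (right) in EN against controls, 1 point per array and 2 arrays per group. By the naming rule, the 4 EN arrays of each gene lie entirely above (left) or below (right) its 4 control arrays, as for Gbp3 (log2 difference 3.30) and Aqp1 (-3.69).

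In all, 139 of 10037 genes were called between EN and controls by limma, 72 higher and 67 lower in EN. Of these, 34 were more than 2-fold higher and 32 more than 2-fold lower. The count was 74 without EN sample 1 replicate 1, 92 and 90 without replicate 1 or 2 of EN sample 2, 89 without EN-KD replicate 1 (37 higher and 52 lower) and 62 without Vector replicate 2. It was 439 with the labelled sample as a random block and 769 when replicate arrays of 4 groups gave the spread.

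Of 26 measured interferon response genes, 7 rose, 0 fell and 19 were not called (11 higher and 0 lower when adjusted over the list alone). The called members included Gbp3, Iigp1, Ifi47 and Gbp2. The list's median log2 difference was 0.23 and its mean 0.73, with camera adjusted p = 3.7e-12 at the preset correlation and adjusted p = 0.607 with an estimated correlation. Of the 26 members, 24 had positive differences. Several classical interferon targets, named here after their values were seen, were not called: Ifit1 differed by 0.47 ± 0.12, Mx2 by 0.25 ± 0.12, Rsad2 by 0.05 ± 0.13 and Stat2 by 0.12 ± 0.12. The simulation recovered only 1.94% of changes of 0.5, so these missing calls do not show that a response was absent. With the dimmer 50% of probe sets left out, 3 of the 7 called members were still tested, and all 3 kept their calls. The other 4 were removed by that filter and so not tested. Of 14 measured macrophage and leukocyte markers, 0 were called by limma (0 adjusted over the list alone), and their median difference was -0.07. The largest among them were Itgb2 (-0.36 ± 0.16) and Adgre1 (-0.29 ± 0.12).

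Of 18 measured genes that report ERK pathway activity, 3 rose and 1 fell (12 and 1 when adjusted over the list alone), with a median log2 difference of 0.53 (camera adjusted p = 6.05e-09; adjusted p = 0.607 with an estimated correlation). Dusp6, the phosphatase that turns off ERK, rose 2.79-fold (log2 1.48 ± 0.12), and Hbegf, a ligand of the EGF receptor, rose 2.33-fold (log2 1.22 ± 0.14). Plaur, the urokinase receptor, rose 1.71-fold, while Dusp1, another phosphatase of MAP kinases, was 1.75-fold lower (log2 -0.80 ± 0.13). Of 28 growth factors and cytokines, 3 rose and 0 fell (5 and 0 over the list alone): Hbegf, Angptl4 (log2 0.79 ± 0.11) and Kitl, the ligand of Kit (log2 0.61 ± 0.12). Their camera adjusted p was 0.0108 (adjusted p = 0.607 with an estimated correlation, and 0.0795 with no filter). Of 14 proteases and invasion genes reported as AP-1 targets, 1 rose (Plaur) and 0 fell (7 and 1 adjusted over the list alone; camera adjusted p = 0.00628 upward, adjusted p = 0.607 with an estimated correlation); the collagen crosslinking enzyme Lox gave -1.19 ± 0.23 (adjusted p = 0.0526). Without the EN sample 2 arrays this list was not called (adjusted p = 0.125). Of 19 AP-1 subunits and immediate early genes, 1 rose (Jun, log2 0.70 ± 0.13, adjusted p = 0.0472) and 0 fell (4 and 3 adjusted over the list alone; camera adjusted p = 0.911). Ier3 gave 0.86 ± 0.21 (adjusted p = 0.106) and Fosl1, chosen after its value was seen, 0.66 ± 0.13 (adjusted p = 0.0526). Leaving out EN sample 1 replicate 1 or Vector replicate 2 ended the calls of Plaur, Dusp1 and Angptl4, at adjusted p from 0.0511 to 0.0794. Jun lost its call without 5 of the 8 arrays (the same pair, both arrays of EN sample 2 and EN-KD replicate 1; adjusted p up to 0.123), and Kitl without any array other than EN sample 1 replicate 2 (adjusted p up to 0.172).

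Of 35 measured fibrillar collagens and matrix proteins, 3 rose and 5 fell (5 and 10 adjusted over the list alone), with a median of -0.12 (camera adjusted p = 0.00594; adjusted p = 0.607 with an estimated correlation). Postn fell most. The fibrillar collagen genes Col5a2 (log2 -1.38 ± 0.21) and Col3a1 (log2 -0.96 ± 0.18, adjusted p = 0.0489) also fell, while Lum, the proteoglycan lumican, rose (log2 0.94 ± 0.13). Of 25 chemokines and NF-kappaB targets, 1 rose (Il33) and 4 fell, among them Cxcl5, Cxcl1 and Ccl7 (2 and 6 adjusted over the list alone), with camera adjusted p = 0.021 downward, adjusted p = 0.607 with an estimated correlation and 0.0795 with no filter. Without EN sample 1 replicate 1 the chemokine list was not called (adjusted p = 0.0572), and Lum was not (adjusted p = 0.0614). Col3a1 lost its call without that array, either array of EN sample 2, EN-KD replicate 1 or Vector replicate 2 (adjusted p up to 0.112).

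Of 28 ATF4 targets and unfolded protein response genes, 0 rose and 1 fell (0 and 2 adjusted over the list alone), with a median of -0.12 (camera adjusted p = 0.00674; adjusted p = 0.607 with an estimated correlation). The called member was Ddit3, a stress-induced transcription factor (log2 -0.70 ± 0.12), and Cebpb gave -0.51 ± 0.11 (adjusted p = 0.0723). The list was not called without the EN sample 2 arrays (adjusted p = 0.218). Of 29 cytosolic ribosomal protein genes, 0 were called (0 adjusted over the list alone; 24 had positive differences), with a median of 0.07 and camera adjusted p = 0.0254 upward (adjusted p = 0.607 with an estimated correlation). Rps25 gave -0.54 ± 0.13 and Rpl14 0.25 ± 0.14, neither called. Quantile normalization ended the ribosomal list's call (adjusted p = 0.358), as did centring arrays on their medians (adjusted p = 0.0737) and leaving out EN sample 1 replicate 2 (adjusted p = 0.133), EN sample 2 replicate 2 (0.154), EN-KD replicate 1 (0.0696) or Vector replicate 2 (0.064). Ddit3 lost its call without EN sample 1 replicate 1, EN sample 2 replicate 2, EN-KD replicate 1 or either Vector array (adjusted p up to 0.0738).

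Of 32 G2/M and mitosis genes, 0 were called by limma (0 over the list alone; camera adjusted p = 0.248), although the list was called lower without the EN sample 1 arrays (adjusted p = 0.0265) or the Vector arrays (adjusted p = 0.037), at the preset correlation only (adjusted p = 0.86 with an estimated correlation and all arrays). The largest differences were Mad2l1 (-0.32 ± 0.13) and Tacc3 (-0.31 ± 0.15). Of 33 G1/S and DNA replication genes, 0 rose and 1 fell (1 and 1 adjusted over the list alone; camera adjusted p = 0.145): Ccnd2 (cyclin D2) was lower (log2 -0.69 ± 0.13), while Ccnd1 (cyclin D1) gave 0.60 ± 0.13 (adjusted p = 0.0675). Of 17 CDK inhibitors and p53 targets, 1 fell (Gadd45g, log2 -0.91 ± 0.13; 0 and 1 over the list alone; camera adjusted p = 0.911), and Cdkn1a gave 0.66 ± 0.22 (adjusted p = 0.225). Ccnd2 lost its call without EN sample 1 replicate 1, either array of EN sample 2, EN-KD replicate 1 or Vector replicate 2 (adjusted p up to 0.109).

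Of 27 growth factor receptors, 0 rose and 3 fell (1 and 3 adjusted over the list alone; camera adjusted p = 0.256): Osmr, the oncostatin M receptor (log2 -1.15 ± 0.17), and the PDGF receptors Pdgfra (log2 -0.91 ± 0.15) and Pdgfrb (log2 -0.77 ± 0.14). Other probe sets gave only -0.40 for Osmr and -0.52 for Pdgfra, and over all probe sets Pdgfra (adjusted p = 0.0591) and Pdgfrb (adjusted p = 0.0887) were not called. Of 22 TGF-beta response genes, 1 rose and 2 fell (2 and 3 adjusted over the list alone; camera adjusted p = 0.923): the ligand Tgfb1 was higher (log2 1.09 ± 0.20), while Id3, an inhibitor of bHLH factors (log2 -1.32 ± 0.13), and the inhibitory Smad6 (log2 -0.66 ± 0.12) were lower. Of 20 IGF and insulin axis genes, 1 fell (Igfbp7, log2 -1.13 ± 0.18, with another probe set at -0.34 and no call over all probe sets, adjusted p = 0.0527; 1 and 2 over the list alone; camera adjusted p = 0.891), and Igf2r gave 0.56 ± 0.14 (adjusted p = 0.116). Pdgfra lost its call without EN sample 1 replicate 1, EN sample 2 replicate 1 or Vector replicate 2 (adjusted p up to 0.0825), Pdgfrb without any array except EN-KD replicate 1 and Vector replicate 1 (up to 0.106), and Smad6 without any array except Vector replicate 1 (up to 0.139). Tgfb1 lost its call without EN sample 1 replicate 1, either array of EN sample 2, EN-KD replicate 1 or Vector replicate 2 (up to 0.202).

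The remaining lists had at most 1 called member, and camera gave them adjusted p from 0.0758 to 0.911. Lpl was the called member of 13 adipocyte markers (0 and 1 over the list alone; Scd1 gave 0.36 ± 0.17). Ogn (log2 -1.66 ± 0.25) was that of 11 chondrocyte and osteoblast markers (0 and 2 over the list alone; Col11a1 gave -0.55 ± 0.13). Mitf (log2 -0.76 ± 0.13) was that of 13 neural and melanocytic markers (0 and 1 over the list alone; S100b gave -0.26 ± 0.14), a call lost without EN sample 1 replicate 1, either array of EN sample 2, EN-KD replicate 2 or Vector replicate 2 (adjusted p up to 0.0872). No member was called among 15 collagen processing and crosslinking enzymes (3 and 4 over the list alone; Lox above, P4ha2 -0.66 ± 0.16), 23 smooth muscle and stress fibre genes (1 and 1; Tpm1 -0.85 ± 0.18, Csrp2 0.52 ± 0.13) or 24 glycolysis and hypoxia genes (0 and 0; Adm -1.51 ± 0.46, Egln3 0.74 ± 0.18). The same held for 33 ribosome biogenesis and MYC targets (0 and 1; Polr1a -0.63 ± 0.13, Srm -0.39 ± 0.17) and 19 cholesterol synthesis genes (0 and 0; Mvk -0.42 ± 0.12, Cyp51 -0.35 ± 0.10). It also held for 10 skeletal muscle markers (1 and 0; Tnnt2 0.67 ± 0.17, Tnni1 0.16 ± 0.14), 13 epithelial markers (1 and 0; Muc1 0.89 ± 0.22 with arrays that overlap between the arms, and 0.24 without EN sample 1 replicate 2; Cldn3 0.29 ± 0.13, with another probe set at -0.76) and 11 endothelial markers (0 and 0; Esam -0.27 ± 0.18, Robo4 -0.20 ± 0.17).

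**Figure D2:**
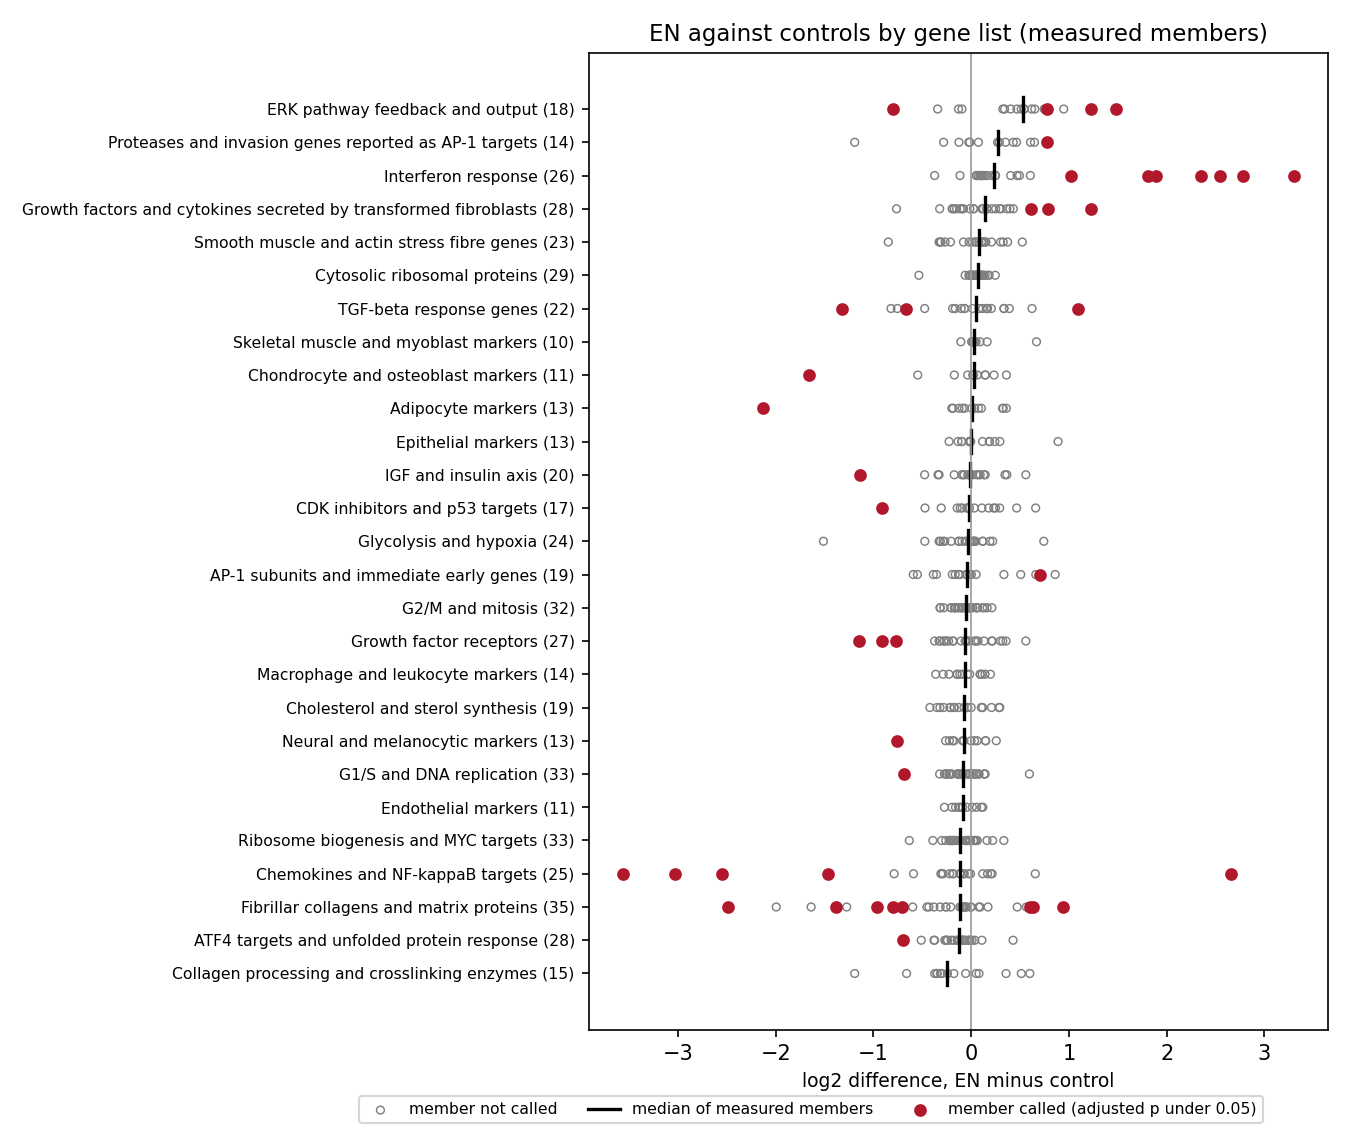
Log2 difference, EN minus control, of each measured member of the 27 tested gene lists, with the number of measured members in brackets. Filled points are members called by limma, open points are not called, and black bars mark medians; the ERK output list has the highest median (0.53), and called interferon response genes all lie above 0.

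Against the kinase-dead control alone, which asks what the kinase activity adds, the leading genes were Upp1 (12.5-fold higher in EN, log2 3.64 ± 0.24), Gbp3 (9.37-fold), Iigp1 (7.67-fold), Il33 (6.85-fold) and Ngef (6.68-fold). Cxcl5 was 17.3-fold lower (log2 -4.11 ± 0.15), Aqp1 13.7-fold, Ptx3 12.8-fold, Cxcl1 12.3-fold and Tfec 10.7-fold, with adjusted p of 2.95e-06 or below for each of these 10 genes over 4 EN and 2 EN-KD arrays. By limma over 8 arrays, 433 genes were called, 209 higher and 224 lower in EN. Of the interferon response genes 7 rose and 0 fell (11 and 1 adjusted over the list alone), and this was the list whose call held with an estimated correlation (adjusted p = 0.0293). Of the ERK output genes 7 rose and 1 fell (11 and 1), and of the matrix genes 4 rose and 12 fell (5 and 15), with adjusted p = 0.278 and adjusted p = 0.636 with an estimated correlation. At the preset correlation camera called 12 lists, 5 higher and 7 lower. Besides these 3, proteases, growth factors and ribosomal proteins were higher (adjusted p from 0.0123 to 0.0249). Glycolysis and hypoxia (22 of 24 members negative, 0.00016), chemokines (0.000393) and collagen processing (0.00113) were lower. So were ATF4 targets (0.0116), G2/M and mitosis (27 of 32 negative, 0.022) and growth factor receptors (0.0433). All these lists had adjusted p of 0.636 or 0.687 with an estimated correlation. Against Vector, hypoxia (median 0.04, camera adjusted p = 0.278) and collagen processing (0.606) were not called. Nor were G2/M and mitosis (0.722), growth factor receptors (0.555) or ribosomal proteins (0.278) called there. Hypoxia and collagen processing were called higher in EN-KD than in Vector, so a rise in EN-KD could give their calls here. The count was 271 and 260 without replicate 1 or 2 of EN sample 2, 197 without EN-KD replicate 1 (79 higher and 118 lower), 290 without EN-KD replicate 2 (193 and 97), 204 with EN sample 1 as the only EN sample and 664 over all probe sets. The balance of directions thus turned with the EN-KD array used. With arrays averaged per labelled sample it was 68.

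Against the empty vector, the control for transduction, Gbp3 was 10.4-fold higher in EN (log2 3.38 ± 0.14), Upp1 7.18-fold, Iigp1 6.20-fold, Il33 5.85-fold and Ifi47 5.68-fold. Aqp1 was 12.2-fold lower (log2 -3.61 ± 0.15), Tfec 8.10-fold, Cxcl5 8.09-fold, Ptx3 7.11-fold and Postn 6.56-fold, with adjusted p of 3.34e-05 or below for each of these genes over 4 EN and 2 Vector arrays. By limma 573 genes were called, 320 higher and 253 lower in EN. Of the interferon response genes 10 rose and 0 fell (11 and 0 adjusted over the list alone; adjusted p = 0.0317 with an estimated correlation), of the ERK output genes 10 rose and 1 fell (13 and 1; adjusted p = 0.239 with an estimated correlation), and of the matrix genes 3 rose and 11 fell (6 and 14; adjusted p = 0.889 with an estimated correlation). At the preset correlation camera called 7 lists, 4 higher and 3 lower: besides these 3, proteases (0.00847) and growth factors (0.0152) higher and ATF4 targets (0.0178) and chemokines (0.0379) lower, with adjusted p of 0.756 or 0.889 with an estimated correlation. The count was 207 without Vector replicate 1, 902 without Vector replicate 2 (411 higher and 491 lower), 352 without EN sample 1 replicate 2 and 292 and 301 without replicate 1 or 2 of EN sample 2. It was 987 over all probe sets, 204 with EN sample 1 as the only EN sample and 61 with arrays averaged per labelled sample.

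The comparison of the controls asks what the protein without its kinase activity changes. EN-KD cells had higher Tmem45a (2.89-fold, log2 1.53 ± 0.21), Col11a2, a fibrillar collagen chain (2.86-fold), Adm, the vasodilator peptide adrenomedullin (2.78-fold, log2 1.48 ± 0.18), Cxcl1 (2.29-fold) and Cxcl5 (2.13-fold) than Vector cells. Cdh3 (P-cadherin) was 4.52-fold lower in EN-KD (log2 -2.18 ± 0.31), Hdc, which makes histamine, 2.44-fold, Rgs16 2.28-fold, Tagln (transgelin) 1.93-fold and G3bp2 1.79-fold. By limma 13 genes were called, 7 higher and 6 lower in EN-KD (801 at an unadjusted p under 0.05). Of 24 glycolysis and hypoxia genes, 23 had positive differences, 3 were called higher (Adm, and Pdk1 and Bnip3 at 0.99 and 0.94, chosen after their values were seen) and 0 lower (6 and 0 adjusted over the list alone). Without EN-KD replicate 1, 0 members were called, and without EN-KD replicate 2, 1 was. The list's median was 0.25 (camera adjusted p = 2.44e-11; adjusted p = 0.672 with an estimated correlation), and 0.12 without Vector replicate 2. Camera also called collagen processing (adjusted p = 0.00104), chemokines (0.0147) and chondrocyte markers (0.0296) higher in EN-KD, with adjusted p of 0.672 or 0.953 with an estimated correlation. The count was 1 without EN-KD replicate 1, 7 without EN-KD replicate 2, 8 without Vector replicate 1, 119 without Vector replicate 2 and 24 over all probe sets. Each of the 10 named calls was lost without at least 1 array, at adjusted p from 0.0506 to 0.289. Cxcl5, Tagln and G3bp2 also lost theirs without either array of EN sample 2, and G3bp2 without either array of EN sample 1, which enter through the shared variance.

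The labels give both EN samples the same construct and do not say how they differ. Dcn, the proteoglycan decorin, was 3.90-fold higher in EN sample 2 than in EN sample 1 (log2 1.96 ± 0.16, adjusted p = 0.000191), Casq2 3.02-fold, Csgalnact1 2.43-fold and Gch1 2.09-fold. Thbs1 (thrombospondin) was 4.58-fold lower in EN sample 2 (log2 -2.20 ± 0.20), the growth factor gene Ptn 4.40-fold, Pde4b 3.24-fold, Col1a1 3.19-fold and the homeobox gene Rhox5 3.17-fold. Malat1 was 4.40-fold higher by the probe set used (log2 2.14 ± 0.27), but with a pseudocount of 1 another probe set stood for the gene and gave 0.02. Likewise a second Col1a1 probe set gave -0.11 against -1.67. Other probe sets gave smaller differences of the same direction for Ptn (-1.10), Pde4b (-0.97), Csgalnact1 (0.80) and Gch1 (0.50). By limma 57 genes were called, 26 higher and 31 lower in EN sample 2, and with arrays centred on their medians 20 were higher and 41 lower. Of 35 matrix genes, 1 rose and 5 fell (1 and 8 adjusted over the list alone; camera adjusted p = 0.00084, adjusted p = 0.942 with an estimated correlation). The count was 11 without EN sample 1 replicate 2, and 9 and 16 without replicate 1 or 2 of EN sample 2. EN sample 1 replicate 2 stood apart from the other arrays on the second principal component. Without EN sample 1 replicate 2, Malat1 (adjusted p = 0.052) was not called; Casq2 lost its call without that array or EN sample 2 replicate 1 (up to 0.135), and Gch1 without either of these or EN sample 2 replicate 2 (up to 0.17).

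**Figure D3:**
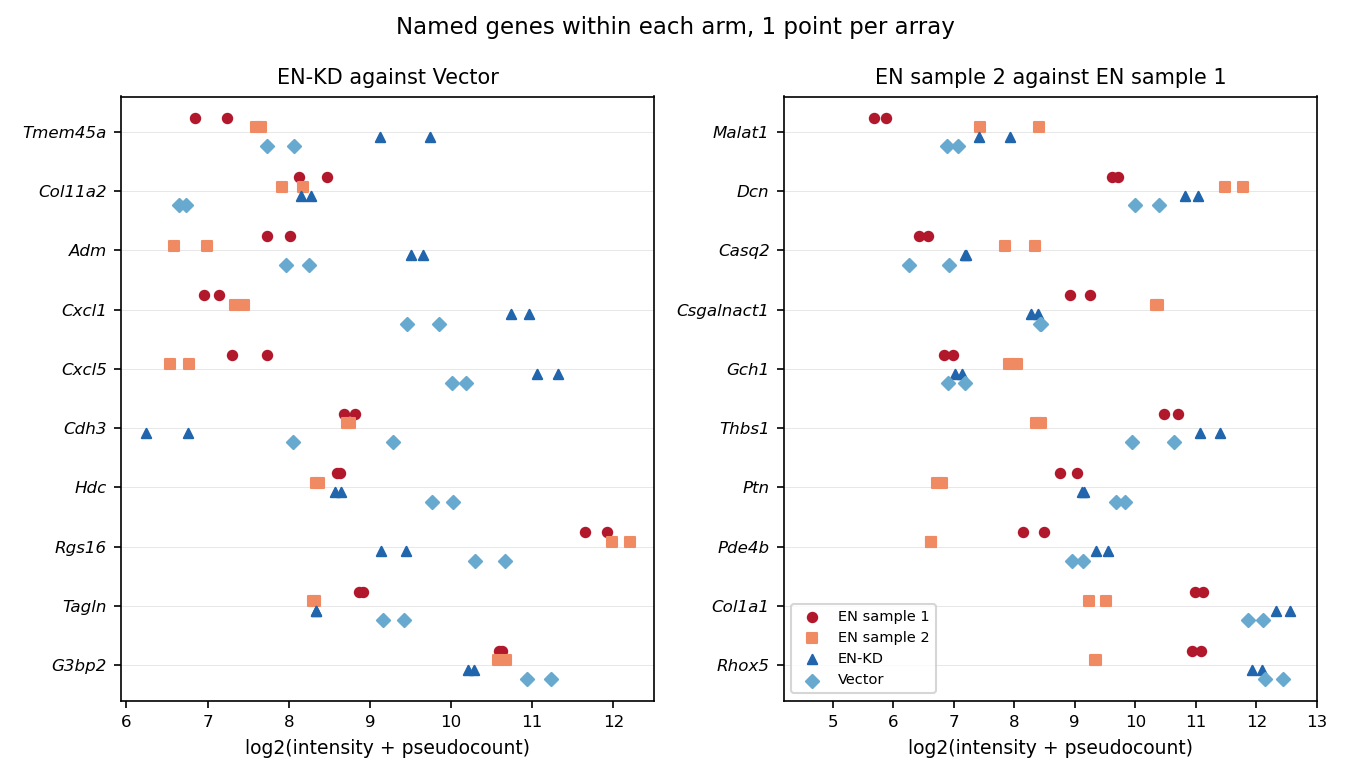
Log2(intensity + pseudocount) of the 10 genes named for EN-KD against Vector (left) and the 10 named for EN sample 2 against EN sample 1 (right), 1 point per array and 2 arrays in each of 4 groups. By the naming rule, the arrays of the compared groups do not overlap within each panel for any gene shown, as for Cdh3 (log2 difference -2.18) and Dcn (1.96).

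The array probe sets for the fusion partners showed no called difference between EN and controls. Etv6 gave -0.11 ± 0.13 (adjusted p = 0.78) and Ntrk3 gave -0.23 ± 0.12 (adjusted p = 0.471). Of the 4 Ntrk3 probe sets, 2 passed the intensity filter, with adjusted p of 0.531 and 0.879 over all probe sets. The labels do not state the species of the transgene or which part these probe sets read, so this does not check the labels.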

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

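The tests of leukocyte markers and of EN sample 1 alone, and leaving out each array for the genes below, were chosen only after the result was seen. By limma's test of EN sample 2 minus EN sample 1, 9 of the genes named for EN against controls differed between the EN samples. The p-values measure only the spread between replicate arrays. Of these 9, Ier3, Lox, Tpm1, Adm and Cdkn1a were not called between EN and controls (limma adjusted p from 0.0526 to 0.225). For them the test shows a difference between 2 samples, not an effect of EN that varies in size. For Adm the 2 controls also differed, by 1.48 (EN-KD minus Vector). Ifi47 rose less in EN sample 2, by a log2 difference of -0.91 ± 0.14 (adjusted p = 0.0132), as did Gbp2 (-0.74 ± 0.14) and Iigp1 (-0.69 ± 0.13). Lox (-0.90 ± 0.13), Col5a2 (-0.69 ± 0.12), Tpm1 (-0.61 ± 0.11) and Adm (-1.08 ± 0.18) were further below controls in EN sample 2. Ier3 (0.77 ± 0.12) and Cdkn1a (0.77 ± 0.15) were further above them. Other probe sets gave -0.07 and -0.67 for Tpm1, -0.49 and -0.77 for Lox and -0.25 for Col5a2. Those of Gbp2, Iigp1 and Cdkn1a gave -0.68, -0.70 and 0.79. Without any 1 EN array the 9 differences stayed at 81% to 119% of their size, but with 1 array left in a sample most calls were lost: 0 genes were still called without EN sample 1 replicate 1, EN sample 1 replicate 2 or EN sample 2 replicate 1, and 1 (Lox) without EN sample 2 replicate 2 (adjusted p up to 0.515). Among gene lists, the camera test at the preset correlation found lower values in EN sample 2 for interferon response (median -0.13, adjusted p = 0.000405), matrix proteins (-0.0857, 0.00084), G2/M and mitosis (-0.11, 0.00687), cholesterol synthesis (-0.10, 0.00687) and smooth muscle genes (-0.077, 0.048). With an estimated correlation 0 of these lists were called. Among the 9 genes, Iigp1 also lost its call without either EN-KD array, which enters through the shared variance.

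The rise of 7 interferon response genes in EN was weighed against technical explanations. Leukocytes or their RNA would raise leukocyte markers, but the mean difference of the 14 measured markers was -0.0565 ± 0.0454 (SE over markers). Of these markers, 5 were positive, up to 0.20 (Cd79a), and 9 were negative. Scaling between arrays was tested by quantile normalization, which left 7 of the 7 called members called. Array medians differed by at most 0.0862 on the log2 scale, so this outcome was nearly fixed in advance. A difference of EN sample 1 alone was tested without shared arrays: the 7 list members called higher in EN sample 1 against EN-KD had a median of 1.9856 ± 0.3371 (SE over genes) in EN sample 2 against Vector, where the median of all genes was -0.0027. The marker values argue against a share of leukocyte RNA large enough to raise them. Mean marker intensities ran from 95.8 (Aif1) to 1140 (Csf1r), against a filter cut of 93.344, so a small share could go unseen. The EN sample 2 values argue against a difference of EN sample 1 alone. The close array medians leave little room for scaling as the source. An effect of the EN kinase, the difference that the design names, may be held as a hypothesis, found and tested on the same data. The labels name no culture or batch that follows the arms, and none was tested.

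The differences in matrix genes between the EN samples were weighed in the same way. Among the 57 called genes, 45 of 47 other probe sets went the same way (95.7%). They come from 31 genes and are not independent, and several lay near 0, such as Malat1 (0.02) and Tpm1 (-0.07). For the called matrix genes 3 of 3 went the same way, although the second probe sets of Col1a1 and Col5a2 gave only -0.11 and -0.25. Quantile normalization left 54 of the 57 genes called, among them all 6 matrix genes. Probe set choice is thus argued against as the source of the directions, but not of the sizes. Array medians differed by at most 0.0862 on the log2 scale, so the outcome under quantile normalization was nearly fixed in advance. Centring arrays on their medians gave 20 genes higher and 41 lower in EN sample 2, against 26 and 31. The close medians leave little room for scaling as the whole source, but the balance of directions moved with centring. The labels name no difference between the EN samples, so no biological explanation was tested, and a difference between cultures or RNA preparations stays open.

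Probe sets without a single gene symbol lay outside the comparisons. Of 1443 such probe sets, 12 were called between EN and controls by limma, 7 higher and 5 lower in EN. The largest increases were 1449009_at (log2 4.83 ± 0.27, from 42.1 to 2110 intensity units) and 1431213_a_at (1.96 ± 0.26), and the largest decreases were 1417185_at (-2.20 ± 0.16) and 1416666_at (-1.34 ± 0.15).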

How the results depend on the processing

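None of the named genes called in a comparison, and none of the lists called between EN and controls, reversed direction under the alternatives tried, while the medians of several uncalled lists near 0 changed sign. Of 46 named genes called in EN against controls, 25 kept the call under every alternative that tested them, as did 10 of 10 for EN against EN-KD, 10 of 10 for EN against Vector, 7 of 10 between the EN samples and 0 of 10 for EN-KD against Vector. The filter at 50% removed, and so did not test, 12 of these 25, 5 for EN against EN-KD and 6 for EN against Vector. Of the 46, 13 lost the call over all probe sets (Rgs16, Jun, Dusp1, Ccnd2, Col3a1, Tgfb1, Smad6, Kitl, Pdgfra, Pdgfrb, Igfbp7, Ddit3, Mitf), 20 without the EN-KD arrays and 14 without the Vector arrays. For EN against controls, pseudocounts, normalizations, filters, probe set choice and the variance trend gave 108 to 158 calls, against 139. Of these 139 genes, 77 were still called over all probe sets and 94 with the filter at 50%, which leaves some untested. How the replicate arrays entered mattered more for the count: 769 calls with 4 group means, 439 with the labelled sample as a random block, 542 with each array as a replicate. The averaged fit has fewer degrees of freedom by construction. The count was 353 without the EN sample 1 arrays, 61 without EN-KD and 68 without Vector; the cause was not tested. For EN against EN-KD it was 664 over all probe sets, 68 with averaged samples and 204 with EN sample 1 alone, against 433. For EN against Vector it was 987, 61 and 204, against 573, and for EN-KD against Vector 24 over all probe sets, against 13. The averaged fits against 1 control take their spread from the 2 EN samples alone. They are the same fits as those for EN against controls without the other control. Over all probe sets more features are tested. Leaving out 1 array at a time gave 62 to 189, 197 to 549, 207 to 902, 1 to 119 and, between the EN samples, 9 to 66 calls, in the order of the comparisons; a lone array is then assumed to vary like the other groups. Of 27 gene lists, 8 were called with the preset correlation and 0 with an estimated one. The estimate has 2 residual degrees of freedom, so few lists could pass with it and the lost calls do not decide. Lists not called with all arrays passed the threshold in some settings that left arrays out, such as ribosome biogenesis without Vector replicate 2 (adjusted p = 0.0102) and glycolysis and hypoxia without the Vector arrays (2e-04).

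Same-numbered arrays deviated together only weakly and in mixed directions (correlations from -0.14 to 0.18), so the replicate numbers do not pair the arrays. With the replicate number as a block the counts were 678 with 4 group means (769 without the block), 373 for EN against EN-KD, 485 for EN against Vector, 11 for EN-KD against Vector and 37 between the EN samples (57 without). Detection calls were not used here, so folds of genes near background rest on the pseudocount.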

Other observations

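Some other called genes, chosen after their values were seen and not tested as groups, follow as values. The cytokine signalling suppressors Socs2 (2.79-fold, log2 1.48 ± 0.12, adjusted p = 0.0011) and Socs3 (1.73-fold, log2 0.79 ± 0.13) were higher in EN. So were the secreted Wnt ligand Wnt5a (3.23-fold, log2 1.69 ± 0.16), the Wnt modulator Dkk2 (2.87-fold, log2 1.52 ± 0.15) and Npnt, the matrix protein nephronectin (3.02-fold). Gfra1, a receptor for GDNF, was 2.25-fold higher, while Artn, a ligand of the same family, was 1.75-fold lower. Cdh11, a mesenchymal cadherin (log2 -1.82 ± 0.26), Slit3 (log2 -1.36 ± 0.16), Mycn (log2 -1.31 ± 0.22) and C1s1, a complement protease (log2 -1.26 ± 0.23), were lower. Socs2 and Wnt5a differed by -0.03 and -0.03 between EN-KD and Vector.

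The test of a culture difference, and leaving out each array for this list and comparison, were chosen only after the data were seen. Of 24 glycolysis and hypoxia genes, 3 were called higher in EN-KD than in Vector (0 without EN-KD replicate 1), with a median log2 difference of 0.2518 over the list (adjusted p = 0.672 with an estimated correlation). Vector replicate 1 stood apart on the third principal component, but without it the median was 0.3843, which argues against that array as the source. Without Vector replicate 2 the median fell to 0.1227, with 19 of 24 members positive. Much of the size thus depends on that array, and the 2 Vector arrays alone give unlike sizes. A difference between the Vector arrays stays open as a source of part of the rise. A difference between the 2 cultures unrelated to the transgene cannot be told apart from an effect of kinase-dead EN, because each control has 1 labelled sample. Culture density or medium age could raise such genes, and neither was tested.

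Chance assignment of arrays was tested on all 35 splits of the 8 arrays into 4 and 4, with each array as a replicate. Only the real split, 1 of 35, gave as many genes: it called 542 and the highest of the other splits called 0. Arrays of a labelled sample are not independent, so this share is only a rough guide. With averaged samples the design has 3 splits, too few for a share under 0.05, and they called 139, 0 and 0 genes.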
